A study of Homo sapiens with 24 samples.

How the data were processed

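Whole-transcriptome libraries of the human lung cancer line HCC827 were measured in 24 samples, 3 in each of 8 groups: DMSO and osimertinib (Osi) for 10 days, and Parental, drug-tolerant persister (DTP) and Resistant cells, each with empty vector (EV) or with overexpression of the circular RNA cATF6 (OC). Per the labels, ribosomal RNA was removed and directional libraries were made in 3 library series: DMSO and Osi, Parental and DTP, and Resistant. The submitters' processing notes name FastQC, STAR, featureCounts and MultiQC with build hg19 and no versions; the strand setting of the counting and the circRNA caller are not given.

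The deposited gene table holds log10(count + 1), not scaled for library size: undoing the log10 gave a whole number in 100% of its cells (tolerance 1e-06). The deposited circRNA table holds log10(reads + 1) of back-splice reads, of which 64.77% above 0 are whole, and the authors' log10 fold changes, p-value and adjusted p-value for Osi against DMSO. A moderated test on the unscaled log10 values, limma without trend, gave back the authors' fold changes to within 5.33e-15. The gene table has 22549 lines. Left out were 2557 entries named NewGene, whose numbering does not match between the table's parts (their correlation was 0.907 between Parental EV and DTP EV and -0.02 between Parental EV and Resistant EV), and 15 symbols that stand in 4 lines each. Of the 19932 genes used, 1788 had no count. A further deposited sheet with 6 gene columns (P1 to P3 and D1 to D3) could not be tied to samples by name and was not used, so osimertinib and DMSO were not compared by gene. In the circRNA sheet the column initials D and O were read as DMSO and Osi.

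Counts were recovered by undoing the log10, scaled by a trimmed mean of M-values (TMM; trims 0.3 and 0.05, written for this work), and compared as log2(scaled count + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, in 1 fit of the 18 Parental, DTP and Resistant libraries. The plan named edgeR for counts, which was not used because the deposited unit is a log10 value, although the recovered counts were whole numbers. The test was thus chosen after the files were opened. Genes with at least 10 counts in at least 3 libraries were tested (15155), and adjusted p 0.05 by the Benjamini-Hochberg method was the threshold. The 6 comparisons were DTP EV and Resistant EV with Parental EV, Resistant EV with DTP EV, and OC with EV in each state, with 2 interactions for a difference in the OC effect from that in Parental cells. circRNAs with at least 2 reads in at least 3 of the 6 libraries were tested the same way (789). A fold change in the text is 2 to the power of the fitted log2 value.

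Totals used ran from 30075330 to 45068508 counts per library. Ratios between replicates varied more than counting allows, with chi-square per degree of freedom from 5.23 to 54.3, so the spread between libraries and not depth sets the precision for abundant genes. Back-splice reads were few, with a mean total of 5603 in DMSO and 7254 in Osi libraries.

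A set of 38 gene lists was tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a set move on balance 1 way with no comparison with other genes, were run beside it. Samples, comparisons, lists, the alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names the 6 genes with the widest rise and the 6 with the widest fall among called genes whose groups do not overlap and whose higher group has a mean of at least 100, up to 3 members of each called list with the smallest p, the 5 circRNAs with the smallest p where none passes, circRNAs of the ATF6 locus, and always ATF6, EGFR, MET, AXL, DUSP6, HSPA5, ITPR1 and ATP2A2. Of these, 4 genes are not reported here. With 3 against 3 libraries, chance alone leaves the groups apart for 10% of genes.

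Alternatives were other scalings (RLE size factors, quantile normalization), no filter, limma without trend, a pseudocount of 0.1, the replicate number as a block, a fit of only the groups compared, a 2-fold minimum, and leaving out each library in turn. Added after the data were seen were voom, leaving out genes listed at 0 in a whole library series, leaving out the 6 Resistant libraries, no scaling or scaling by total circRNA reads for circRNAs, and leaving out each library for the lists. The steps were tested on simulated data made with no list changed and 200 genes changed per comparison. Changes of 4-fold were recovered for 78.8 to 89.4% of genes and changes of 1.5-fold for 55.2 to 62.7%, 2.74 to 7.74% of calls fell on unchanged genes, and no list was called. The simulated genes varied independently of each other, so this cannot show how often lists with correlated members are called falsely. Each gene was given 1 spread in all groups, although real replicates differed most in DTP EV. Only 200 genes changed, far fewer than limma called in the real data. These rates therefore need not hold for the real comparisons, in particular those with DTP EV. For simulated circRNAs 2.99% of 2-fold, 46.3% of 4-fold and 65.2% of 8-fold changes were recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.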

Results

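The series concerns HCC827 cells, a human lung adenocarcinoma line with an activating EGFR mutation, and osimertinib, a kinase inhibitor that blocks mutant EGFR. Gene counts were compared in Parental cells, in drug-tolerant persister (DTP) cells and in cells with acquired resistance (Resistant), each carrying an empty vector (EV) or overexpressing the circular RNA cATF6 (OC), with 3 libraries in each of the 6 groups. Circular RNAs were compared in 3 libraries after 10 days of DMSO and 3 after 10 days of osimertinib (Osi). The labels do not state that replicates came from separate cultures, so every p-value measures only a spread between libraries. For genes, that spread was pooled over the 18 libraries of the 6 groups and is not that of the groups compared. Replicates differed most in DTP EV (chi-square per degree of freedom 16.6 to 54.3, against 5.23 to 7.17 in Parental EV), so p-values for DTP comparisons can be too small. Levels are scaled counts (mean ± SD, n = 3 libraries), and changes are log2 fold changes with their standard error (SE).

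To see how far the overexpression reached the ATF6 gene, its counts were compared first. ATF6 encodes a sensor of unfolded protein in the endoplasmic reticulum (ER). Its level was 2933 ± 58.5 in Parental EV and 18080 ± 331 in Parental OC, 3279 ± 14.9 and 20860 ± 1920 in DTP EV and OC, and 2094 ± 196 and 32120 ± 914 in Resistant EV and OC. The rise with OC was 6.16-fold in Parental (log2 2.62, SE 0.06), 6.34-fold in DTP and 15.4-fold in Resistant cells (log2 3.94). The rise was larger in Resistant than in Parental cells by 1.32 on the log2 scale (adjusted p = 3.83e-08), and that in DTP cells differed from Parental by 0.04 (adjusted p = 0.842). A count per gene does not separate circular from linear transcripts of ATF6.

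**Figure D1:**
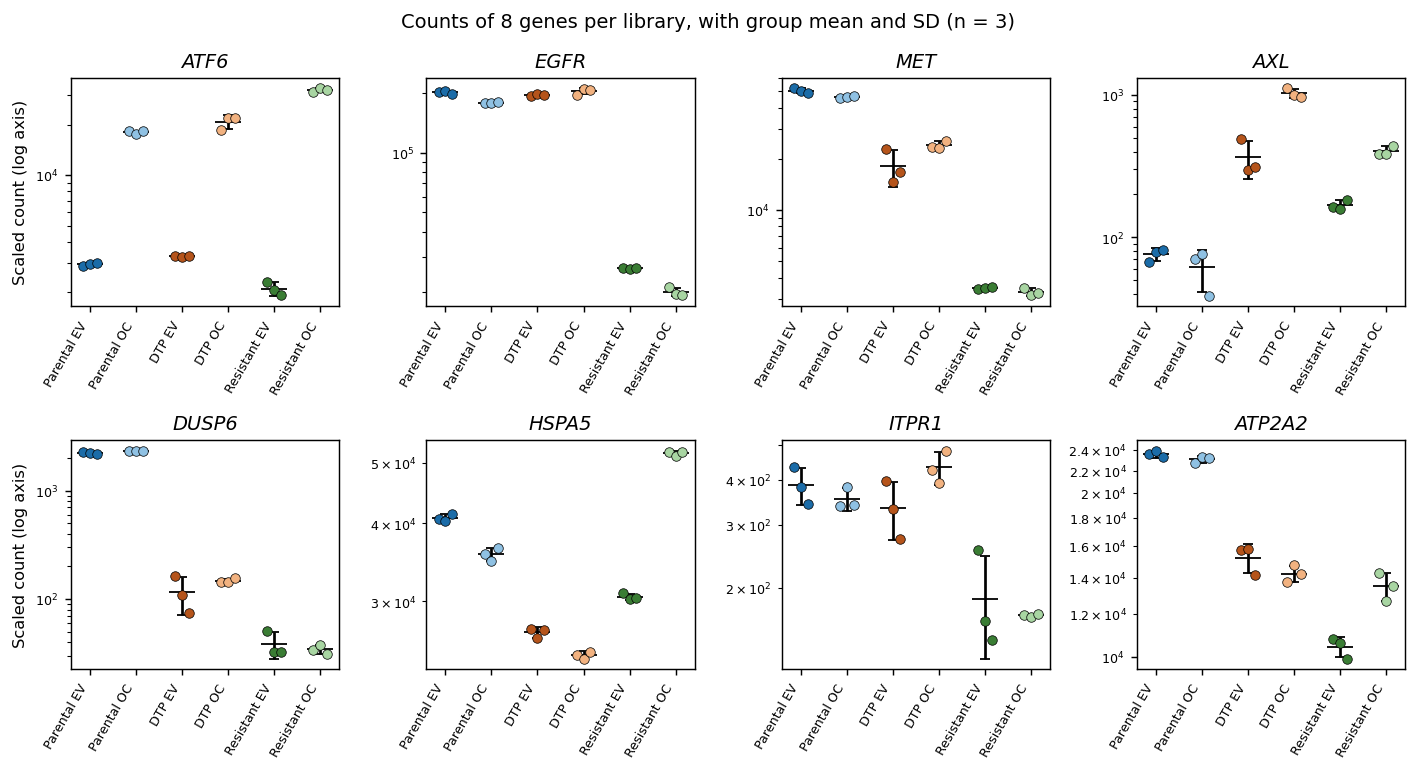
Levels of ATF6, EGFR, MET, AXL, DUSP6, HSPA5, ITPR1 and ATP2A2 in the 6 groups. Scaled counts on a log axis, mean ± SD, n = 3 libraries per group; dots are single libraries.

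Resistant libraries lay far from the other 12. The first principal component held 75.9% of the variance and separated the 6 Resistant libraries, and the second held 11%. AZGP1 (a secreted glycoprotein, 7126 ± 288 in Parental EV), TOX3 (a transcription factor, 4744 ± 200) and DSCAML1 (an adhesion protein, 3926 ± 167) were listed at 0 in Resistant EV. SRGN, a granule proteoglycan, had 8724 ± 274 in Resistant EV and was listed at 0 in Parental EV and DTP EV. Whether a 0 listed across a whole library series is an absence of reads or a gap in the table was not settled. Of 9299 genes with at least 300 counts in each of the 12 Parental and DTP libraries, 50 were listed at 0 in all 6 Resistant libraries. Another 8 genes were the reverse: ALDH3A1, C14orf132, EPHB6, MAL, NR0B1, PLCXD3, SRGN and UGT1A4. No gene was at 0 in all 6 DTP libraries and at 300 counts or more in all 6 Parental libraries, a plain count of genes with no test behind it. Resistant libraries carry their own library series, so state and series cannot be told apart in any comparison of Resistant cells with the other states.

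**Figure D2:**
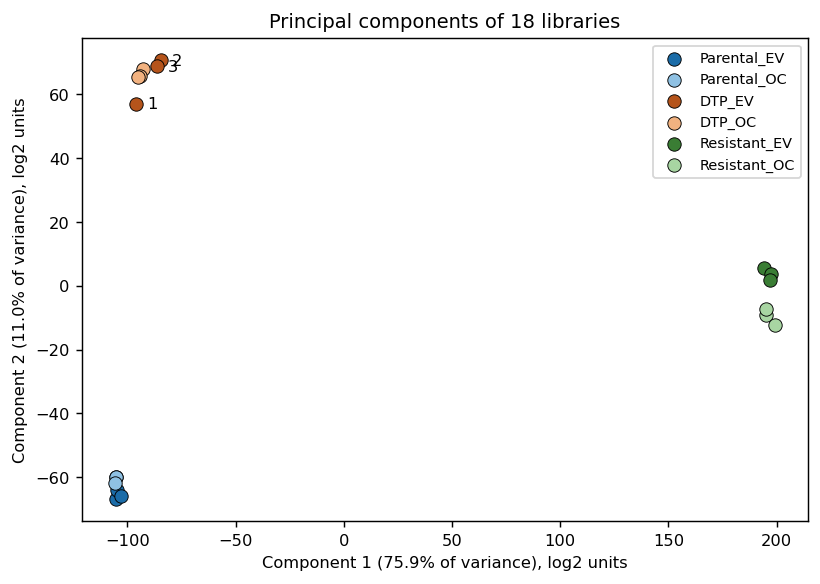
Principal components of 18 libraries. Scaled log2 counts of the genes tested; each point is 1 library, coloured by group.

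To describe the drug-tolerant state, DTP EV was compared with Parental EV. DUSP6, a phosphatase induced by ERK signalling, fell 19.9-fold from 2214 ± 60.1 to 116 ± 44.3 (log2 -4.32, SE 0.22). EGR1, an immediate ERK target, fell 89.3-fold (log2 -6.48, SE 0.27), DUSP5, another ERK phosphatase, 18.5-fold (log2 -4.21, SE 0.13) and EREG, an EGFR ligand, 8.77-fold (log2 -3.13, SE 0.16). EGFR itself stood at 201200 ± 3750 and 194900 ± 1710 (log2 -0.05, SE 0.05, adjusted p = 0.434), with the sign turning under quantile normalization (0.05, adjusted p = 0.589) and adjusted p from 0.291 to 0.653 over all alternatives. MET, a receptor that can bypass EGFR, fell 2.83-fold (log2 -1.50, SE 0.11), and AXL, a receptor linked to drug tolerance, rose 4.66-fold (log2 2.22, SE 0.22). TOP2A, a mitotic topoisomerase, fell 7.32-fold (log2 -2.87, SE 0.18) and TPX2, a spindle factor, 3.66-fold (log2 -1.87, SE 0.13). ATF6 differed by 0.16 (SE 0.06, adjusted p = 0.0406), with adjusted p from 0.00459 to 0.112 over its alternatives, a call lost when any single Parental EV or DTP EV library was left out: adjusted p = 0.112, 0.0786 and 0.063 without Parental EV 1, 2 and 3, and 0.0608, 0.0724 and 0.0886 without DTP EV 1, 2 and 3.

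The gene lists moved with these genes. Of 28 genes of EGFR-MAPK output, 22 fell and 2 rose (the same adjusted over the list alone, camera adjusted p = 2.18e-07, adjusted p = 0.295 with an estimated correlation). All 34 genes of G2 and mitosis fell (34 adjusted over the list alone, adjusted p = 1.13e-15, adjusted p = 0.277 with an estimated correlation), as did 28 of 34 S phase genes (28, adjusted p = 5.47e-08, adjusted p = 0.332 with an estimated correlation). NF-kB and inflammatory genes fell in 25 of 31 (25, adjusted p = 5.62e-11): PTGS2, the inducible prostaglandin synthase, 20.3-fold and BIRC3, an inhibitor of apoptosis, 5.55-fold. Glycolysis and hypoxia genes fell in 30 of 32 (30, adjusted p = 2.46e-17): HK2, the enzyme of the first glycolytic step, 5.34-fold and VEGFA 3.47-fold. YAP-TEAD targets rose in 18 of 23 (18, adjusted p = 2.6e-09), with CYR61, a matricellular protein, up 4.17-fold. Of 17 lists called, these last 3 held with an estimated correlation (NF-kB 0.00174, glycolysis and hypoxia 0.0441, YAP-TEAD 0.000563).

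TGFB2, a cytokine, rose 9.46-fold (log2 3.24, SE 0.08) and THBS1, a matrix protein, 23.8-fold with 24 of 42 mesenchymal genes up and 8 down (24 and 8, adjusted p = 0.003, adjusted p = 0.332 with an estimated correlation). Fibroblast markers rose in 5 of 11 and fell in 2 (5 and 2, median 1.19, adjusted p = 0.409) and endothelial markers rose in 3 of 7 and fell in 2 (3 and 2, median 0.88, adjusted p = 0.847). CTSA, a lysosomal protease, rose 1.99-fold with 27 of 39 lysosome and autophagy genes (27, adjusted p = 9.91e-06, adjusted p = 0.0743 with an estimated correlation). MT-ND1, a complex I subunit made in mitochondria, rose 1.72-fold with 7 of 13 genes of the mitochondrial genome (7, adjusted p = 0.0179, adjusted p = 0.557 with an estimated correlation). HSP90B1, an ER chaperone, fell 1.83-fold and HSPA5, the main ER chaperone, 1.53-fold (log2 -0.61, SE 0.03); ATF6 and XBP1 targets fell in 16 of 28 and rose in 6 (16 and 7, adjusted p = 0.018, adjusted p = 0.277 with an estimated correlation). DDIT4, a stress gene, fell 7.58-fold and GDF15, a stress-induced cytokine, 13.9-fold. ATP2A2, the ER calcium pump, fell 1.55-fold (log2 -0.63, SE 0.05), and ITPR1, an ER calcium release channel, was not called (log2 -0.22, SE 0.18, adjusted p = 0.323). SQLE, an enzyme of cholesterol synthesis, rose 2.17-fold.

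The widest changes lay at genes near 0 in 1 of the groups, where levels are given in place of folds. NOTUM, a Wnt-inactivating enzyme, stood at 774 ± 339 in DTP EV and 2.94 ± 2.99 in Parental EV, LBH, a transcription cofactor, at 1447 ± 589 and 5.87 ± 1.78, and CLIC5, a chloride channel protein, at 361 ± 239 and 1.68 ± 2.91. KCNH1, a potassium channel (255 ± 125), and NPPB, a natriuretic peptide (208 ± 26.5), had no read in Parental EV, and SCHIP1, a cytoskeletal adaptor (224 ± 76.1), had 2. SERPINB4, a squamous protease inhibitor, stood at 22 ± 11.9 in DTP EV and 5001 ± 179 in Parental EV and its paralog SERPINB3 at 7.9 ± 13.7 and 2069 ± 63.5; reads between the pair are hard to assign. OLFM4, a secreted glycoprotein, stood at 307 ± 511 and 8599 ± 130, S100A8, a calcium-binding alarmin, at 13.7 ± 8.03 and 1789 ± 83.1, and CES1, a carboxylesterase, at 2.88 ± 2.5 and 299.8 ± 9.79. The OLFM4 change was -9.39 without DTP EV 1, -6.24 without DTP EV 2 and -6.41 without DTP EV 3. The readthrough NME1-NME2, whose reads overlap both of its genes, stood at 125 ± 216 and 1324 ± 166 and lost its call without DTP EV 1 (adjusted p = 0.0605) or DTP EV 3 (adjusted p = 0.068). By limma, 8647 of 15155 genes passed adjusted p 0.05, 4356 higher and 4291 lower in DTP EV, and 2699 of them changed at least 2-fold.

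Acquired resistance was compared with the Parental state in the same way. EGFR fell 7.69-fold, from 201200 ± 3750 in Parental EV to 26170 ± 261 in Resistant EV (log2 -2.94, SE 0.05), MET 14.5-fold to 3479 ± 57 (log2 -3.86, SE 0.11) and DUSP6 56.8-fold to 38.9 ± 10.7 (log2 -5.83, SE 0.22). IFIT1, an interferon-induced antiviral protein, rose 218-fold from 726.5 ± 29.8 to 158800 ± 3510 (log2 7.77, SE 0.12) and IFIT2, of the same family, to 226900 ± 3600. AKR1C1, an NRF2-driven reductase, rose from 63.3 ± 6.27 to 121500 ± 1050 (log2 10.89, SE 0.20). HLA-E, a class I antigen-presenting molecule, rose 16.7-fold (log2 4.06, SE 0.05) and TAP1, a peptide transporter, 17.7-fold (log2 4.14, SE 0.06). TOP2A fell 62.6-fold to 647.5 ± 78 and RRM1, a subunit of ribonucleotide reductase, 4.88-fold.

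Of 42 interferon response genes, 41 rose (41 adjusted over the list alone, camera adjusted p = 6.47e-17, adjusted p = 0.26 with an estimated correlation). NRF2 and redox genes rose in 24 of 27 (24, adjusted p = 1.09e-06, adjusted p = 0.171 with an estimated correlation) and antigen presentation genes in 15 of 23, with 6 lower (15 and 6, adjusted p = 0.00122, adjusted p = 0.143 with an estimated correlation). EGFR-MAPK output fell in 24 of 28 (24, adjusted p = 5.74e-05, adjusted p = 0.434 with an estimated correlation), with the EGFR ligand AREG down 82.5-fold. G2 and mitosis genes fell in 34 of 34 (34, adjusted p = 3.59e-10, adjusted p = 0.434 with an estimated correlation). CXCL8, a neutrophil chemokine, fell 55.7-fold with 22 of 31 NF-kB and inflammatory genes (22, adjusted p = 0.00511, adjusted p = 0.171 with an estimated correlation). ASNS, an ATF4 target that makes asparagine, fell 9.68-fold with 21 of 27 PERK and ATF4 targets (21, adjusted p = 0.000218, adjusted p = 0.274 with an estimated correlation). NPC2, a lysosomal cholesterol carrier, rose 7.28-fold, SQLE rose 3.98-fold and PDK1, a hypoxia-induced kinase, fell 16.6-fold. RPL7, which has many pseudogenes that can take its reads, fell 18.7-fold with 44 of 53 ribosomal protein genes (44, adjusted p = 1.09e-06, adjusted p = 0.539 with an estimated correlation). Ribosomal protein genes took 1.88 to 2.46% of the counts in the 6 Resistant libraries and 3.69 to 4.83% in the other 12. None of the 13 lists called held with an estimated correlation, and fry, which asks whether the genes of a set move on balance 1 way without comparing them with other genes, called 35.

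At the extremes, OLR1, a scavenger receptor (47390 ± 1510), and IGFBP5, which binds insulin-like growth factors (12600 ± 288), were listed at 0 in Parental EV. TIMP3, an inhibitor of matrix proteases, stood at 75650 ± 834 against 3.81 ± 2, SULF2, a heparan sulfate sulfatase, at 32750 ± 794 against 3.32 ± 2.96, and KLK5, a serine protease, at 12270 ± 598 against 2 reads. CXCL5, a chemokine, stood at 11.9 ± 16.5 against 104600 ± 4620; its change was -15.39 without Resistant EV 1 and -12.91 without Resistant EV 3. FGB, a fibrinogen chain (4905 ± 119 in Parental EV), and SERPINB4 were listed at 0 in Resistant EV, FGB in all 6 Resistant libraries. HSPA5 fell 1.34-fold (log2 -0.42, SE 0.03), ATF6 1.40-fold, ATP2A2 2.26-fold (log2 -1.18, SE 0.05) and ITPR1 2.12-fold (log2 -1.08, SE 0.18), and AXL rose 2.20-fold (log2 1.14, SE 0.22). Limma called 12479 of 15155 genes, 5853 higher and 6626 lower in Resistant EV, of which 7393 changed at least 2-fold.

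Set against the drug-tolerant state, Resistant EV again showed lower EGFR, 7.45-fold below DTP EV (log2 -2.90, SE 0.05), and lower MET (5.11-fold, log2 -2.35, SE 0.11), AXL (2.11-fold) and MYC, a growth-promoting transcription factor (6.12-fold, log2 -2.61, SE 0.10). IFIT3, an interferon-induced protein, rose 66.4-fold (log2 6.05, SE 0.09), with 41 of 42 interferon response genes up (41 adjusted over the list alone, camera adjusted p = 1.2e-17, adjusted p = 0.265 with an estimated correlation). AKR1C1 stood at 121500 ± 1050 against 52.1 ± 23.4, with 25 of 27 NRF2 and redox genes up (25, adjusted p = 9.77e-10, adjusted p = 0.135 with an estimated correlation). XBP1, a transcription factor of the ER stress response, rose 7.76-fold (log2 2.96, SE 0.05), with 20 of 28 ATF6 and XBP1 targets up and 3 down (20 and 3, adjusted p = 0.00151, adjusted p = 0.135 with an estimated correlation). HSPA5 rose 1.14-fold (log2 0.19, SE 0.03), a direction that turned under quantile normalization (log2 -0.24, adjusted p = 3.25e-05, against 1.89e-05 to 0.0182 over its alternatives). ATF6 fell 1.57-fold, ATP2A2 1.46-fold, ITPR1 1.82-fold and DUSP6 2.85-fold, and HLA-E rose 13.7-fold.

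G2 and mitosis genes fell in 31 of 34 (31 adjusted over the list alone, adjusted p = 2.8e-05, adjusted p = 0.705 with an estimated correlation), and MCM2, a replication helicase subunit, fell 4.22-fold. EGFR-MAPK output fell in 19 of 28 (20, adjusted p = 0.0491, adjusted p = 0.738 with an estimated correlation), a call lost without DTP EV 1 (0.0699), Resistant EV 2 (0.0627) or Resistant EV 3 (0.0577). UGT1A6, a glucuronidation enzyme whose last exons are shared by its family (20590 ± 453), MAL, a membrane raft protein (7523 ± 129), and ALDH3A1, an aldehyde dehydrogenase (6609 ± 173), were listed at 0 in DTP EV, MAL and ALDH3A1 in all 12 Parental and DTP libraries, and APOD, a lipid carrier (8666 ± 161), had 3. PSCA, a surface antigen, stood at 36080 ± 2240 against 8.81 ± 5.95 and changed by 11.43 without DTP EV 3. SLC34A2, a phosphate transporter of alveolar cells (5971 ± 1500 in DTP EV), OR2I1P, an olfactory receptor pseudogene (3393 ± 725), ANOS1, an extracellular matrix protein (3752 ± 2040), and UNC13B, a vesicle-priming protein (2858 ± 790), were listed at 0 in Resistant EV, OR2I1P in all 6 Resistant libraries, and BICC1, an RNA-binding protein (8314 ± 1120), had 4. CXCL5 stood at 74770 ± 10100 in DTP EV. Limma called 12239 genes, 5696 higher and 6543 lower in Resistant EV, 6917 of them at least 2-fold; none of the 10 lists called held with an estimated correlation and fry called 35.

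To see what cATF6 overexpression changed before drug exposure, Parental OC was compared with Parental EV. TNFAIP3, a feedback inhibitor of NF-kB, fell 2.78-fold from 11680 ± 127 to 4199 ± 213 (log2 -1.48, SE 0.05), CXCL8 3.01-fold (log2 -1.59, SE 0.13) and ICAM1, an adhesion receptor, 1.93-fold (log2 -0.95, SE 0.06). The cytokines TNF and IL23A fell 3.84-fold and 3.82-fold, GDF15 3.47-fold, and DUSP1, a phosphatase of stress kinases, 3.81-fold (log2 -1.93, SE 0.10). NUAK2, a kinase and YAP target, fell 3.36-fold (log2 -1.75, SE 0.08) and CYR61 2.26-fold. SQSTM1, an autophagy receptor, fell 1.98-fold (log2 -0.99, SE 0.07) and NEU1, a lysosomal sialidase, 1.65-fold. TXNIP, a glucose-responsive inhibitor of thioredoxin, rose 2.27-fold (log2 1.18, SE 0.14) and its relative ARRDC4 2.16-fold, as did LHX4, a homeobox factor (2.20-fold). INSIG1, a regulator of cholesterol synthesis, rose 1.93-fold, SCD, a fatty acid desaturase, 1.48-fold, and MT-CO3, a mitochondrially encoded oxidase subunit, 1.70-fold.

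NF-kB and inflammatory genes fell in 25 of 31 (26 adjusted over the list alone, camera adjusted p = 1.91e-25), YAP-TEAD targets in 12 of 23 (12, adjusted p = 5.79e-06) and lysosome and autophagy genes in 13 of 39 (16, adjusted p = 2.54e-08); these 3 of 16 lists called held with an estimated correlation (4.44e-05, 0.00293 and 0.0224). Interferon response genes fell in 18 of 42 (24, adjusted p = 1.28e-09, adjusted p = 0.291 with an estimated correlation), with TRIM22, an antiviral protein, down 2.26-fold (a call lost under voom at 0.0633) and IFI6, a mitochondrial interferon-induced protein, 1.68-fold. S phase genes rose in 9 of 34 (10, adjusted p = 3.59e-07, adjusted p = 0.361 with an estimated correlation), with cyclin CCNE2 up 2.01-fold. The p53 list fell in 7 of 22 (7, adjusted p = 0.00343, adjusted p = 0.114 with an estimated correlation), with GADD45A, a DNA damage response gene, down 2.00-fold, and the death-promoting BBC3 fell 2.01-fold. Mitochondrial genome genes rose in 8 of 13 (10, adjusted p = 1.32e-08, adjusted p = 0.236 with an estimated correlation). EGFR-MAPK output fell in 4 of 28 (8, adjusted p = 0.0104, adjusted p = 0.549 with an estimated correlation), with DUSP5 down 2.58-fold and DUSP6 not called (log2 0.06, SE 0.22, adjusted p = 0.914).

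EGFR was lower by 1.13-fold in Parental OC (log2 -0.18, SE 0.05, adjusted p = 0.0187), a call lost without Parental EV 1 (0.0805) or 2 (0.0863), without Parental OC 1 (0.079) or 2 (0.0673), under quantile normalization (0.112) and without the 6 Resistant libraries (0.0621), with 0.000194 the lowest over its alternatives. MET (log2 -0.13, SE 0.11, adjusted p = 0.506) and AXL (log2 -0.36, SE 0.22, adjusted p = 0.336) were not called, though MET was when only the 6 Parental libraries were fitted (adjusted p = 0.00351, against 0.737 at the highest of its alternatives). HSPA5 fell 1.15-fold (log2 -0.19, SE 0.03). ITPR1 (log2 -0.12, SE 0.18, adjusted p = 0.75) and ATP2A2 (log2 -0.03, SE 0.05, adjusted p = 0.767; 0.02 under quantile normalization) were not called. CEACAM7, an epithelial adhesion protein, fell 4.83-fold (log2 -2.27, SE 0.41), and AQP9, a water channel, fell 4.98-fold (log2 -2.32, SE 0.60), a call lost without Parental EV 1 (0.0539) or Parental OC 2 (0.0622) and at a pseudocount of 0.1 (0.178). TOMM6, a short gene of the mitochondrial import complex that overlaps its neighbours, rose 5.76-fold (log2 2.53, SE 0.66), with 1.88 and adjusted p = 0.0939 without Parental EV 1, 2.23 and 0.0755 without Parental EV 2, 3.48 without Parental EV 3, and adjusted p = 0.0636 and 0.0507 without Parental OC 1 and 3. The readthrough MINOS1-NBL1 rose 3.09-fold, a call lost without Parental EV 3 (0.0594) or Parental OC 1 (0.0685) or 2 (0.0504). Limma called 2135 genes, 915 higher and 1220 lower, 168 of them at least 2-fold; the count was 1389 without Parental EV 1 and 5698 when only the 6 Parental libraries were fitted.

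In drug-tolerant cells, DTP OC was compared with DTP EV. AXL rose 2.87-fold, from 367 ± 108 to 1027 ± 79.5 (log2 1.52, SE 0.22). LCN2, an iron-binding secreted protein, fell 1.87-fold from 107700 ± 16200 to 57320 ± 2810 (log2 -0.90, SE 0.08), and the mucins MUC20 and MUC1 fell 2.27-fold and 1.62-fold. The epithelial genes CDH3, a cadherin, and ELF3, a transcription factor, each fell 1.42-fold (log2 -0.51 and -0.50, SE 0.04 and 0.05). RNASE1, a secreted ribonuclease, fell 5.74-fold (log2 -2.52, SE 0.47) and IYD, an iodotyrosine deiodinase, 2.89-fold. NDC80, a kinetochore protein, rose 2.48-fold (log2 1.31, SE 0.19), TTK, a spindle checkpoint kinase, 2.03-fold (log2 1.02, SE 0.15), and PCNA, a replication clamp, 1.50-fold, with CCND1, the G1 cyclin, up 1.47-fold, BRCA1, a DNA repair gene, 1.74-fold and LDHA, lactate dehydrogenase, 1.47-fold. COL5A1, a collagen chain, rose 2.40-fold, AGR2, an ER protein of secretory cells, fell 1.82-fold, and CTSH, a lysosomal protease, fell 1.52-fold.

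How many genes were called in DTP cells rested on single libraries and on the libraries fitted. Limma called 2785 genes, 1445 higher and 1340 lower, 266 of them at least 2-fold, but 4654 without DTP EV 1, 1820 without DTP EV 2, 1485 without DTP EV 3 and 1499 without DTP OC 3. DTP EV 1 lay apart from its replicates: chi-square per degree of freedom against DTP EV 2 and 3 was 54.3 and 53.7, against 16.6 between those 2 and 5.23 to 7.17 in Parental EV. With only the 6 DTP libraries fitted, 65 genes were called, 13 higher and 52 lower. Of the genes named for DTP OC, ATF6, AXL, LCN2, MUC20, MUC1, CDH3, ELF3, RNASE1 and IYD then kept adjusted p below 0.05 (from 1.14e-05 to 0.0448), and the others that had been called did not. IGFBP5 rose 7.27-fold (log2 2.86, SE 0.46; 3.58 without DTP EV 1), TIMP3 4.26-fold (log2 2.09; 2.88 without it) and GBP4, an interferon-induced GTPase, 3.40-fold, while KRT4, an epithelial keratin, fell 3.72-fold (log2 -1.90; -2.61 without DTP EV 1) and TMPRSS2, a surface protease, 3.01-fold.

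The remaining genes named for DTP OC also rested on single libraries, and 3 of them on the pseudocount: at 0.1 adjusted p was 0.302 for TRABD2A, 0.223 for ETV1 and 0.274 for DEFB4A. TRABD2A, a Wnt-cleaving protease, rose 4.02-fold and lost its call without DTP EV 2 (0.0704) or 3 (0.119) and DTP OC 1 (0.0534) or 3 (0.102). ETV1, an ERK-responsive transcription factor, rose 3.52-fold (log2 1.82; 2.43 without DTP EV 1) and lost it without DTP EV 2 (0.101) or 3 (0.109) and DTP OC 1 (0.0563), 2 (0.0586) or 3 (0.0575). SLC16A7, a lactate transporter, fell 3.56-fold (log2 -1.83; -2.56 without DTP EV 2), with adjusted p = 0.0596, 0.105, 0.0683 and 0.0565 without DTP EV 1, DTP EV 3, DTP OC 1 and DTP OC 3. DEFB4A, an antimicrobial defensin, fell 3.26-fold, with adjusted p = 0.128, 0.127, 0.0658, 0.0873 and 0.101 without DTP EV 2, DTP EV 3, DTP OC 1, 2 and 3, and 0.0586 without trend. MET rose 1.36-fold (log2 0.44, SE 0.11, adjusted p = 0.0508 without DTP OC 3) and HSPA5 fell 1.09-fold (log2 -0.12, SE 0.03, adjusted p = 0.0659, 0.0543, 0.0635 and 0.0544 without DTP EV 3, DTP OC 1, 2 and 3). EGFR (log2 0.06, SE 0.05, adjusted p = 0.407), ITPR1 (log2 0.39, SE 0.18, adjusted p = 0.159), ATP2A2 (log2 -0.10, SE 0.05, adjusted p = 0.213) and DUSP6 (log2 0.41, SE 0.22, adjusted p = 0.208; 0.69 and adjusted p = 0.0103 without DTP EV 1) were not called.

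Member counts for the lists in DTP cells come from the fit of all 18 libraries. With only the 6 DTP libraries fitted, limma did not call NDC80, TTK, PCNA or BRCA1 (adjusted p = 0.0516, 0.051, 0.0676 and 0.0591). The epithelial genes CDH3 and ELF3 kept their calls there (0.0392 each). G2 and mitosis genes rose in 33 of 34 with OC in DTP cells (33 adjusted over the list alone, camera adjusted p = 5.7e-21, adjusted p = 0.196 with an estimated correlation) and S phase genes in 30 of 34 (32, adjusted p = 4.62e-16, adjusted p = 0.196 with an estimated correlation). Epithelial genes fell in 25 of 32 (27, adjusted p = 1.75e-19, adjusted p = 0.103 with an estimated correlation), and mesenchymal genes rose in 18 of 42 (21, adjusted p = 6.88e-08, adjusted p = 0.148 with an estimated correlation), beside 1 of 11 fibroblast markers (1, median 0.70, adjusted p = 0.157). EGFR-MAPK output rose in 13 of 28 (14, adjusted p = 0.000282, adjusted p = 0.472 with an estimated correlation) and glycolysis and hypoxia in 15 of 32 (19, adjusted p = 0.000246, adjusted p = 0.387 with an estimated correlation). The airway goblet, club and ciliated list, which holds MUC20, MUC1 and AGR2, fell in 6 of 20 (8, adjusted p = 0.000282) and was the only 1 of 12 lists called to hold with an estimated correlation (0.0359). NF-kB and inflammatory genes fell in 8 of 31 and rose in 2 (9 and 2, adjusted p = 0.00553, adjusted p = 0.196 with an estimated correlation), a call lost without DTP EV 1 (0.101).

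In resistant cells, Resistant OC was compared with Resistant EV. HSPA5 rose 1.70-fold, from 30490 ± 340 to 51850 ± 480 (log2 0.77, SE 0.03), CALR, a calcium-binding ER chaperone, 1.39-fold to 81230 ± 2450 (log2 0.47, SE 0.06) and HYOU1, an ER chaperone, 1.41-fold. ATP2A2 rose 1.29-fold (log2 0.37, SE 0.05). EGLN3, an oxygen-sensing hydroxylase, rose 4.20-fold (log2 2.07, SE 0.07), P4HA1, a collagen hydroxylase, 4.06-fold (log2 2.02, SE 0.07), ANGPTL4, a hypoxia-induced secreted protein, 5.25-fold and DDIT4 3.88-fold (log2 1.96, SE 0.08). FTH1, the ferritin heavy chain, rose 2.17-fold to 374700 ± 15300, and TNFAIP2 and TNFAIP3, both induced by TNF, 1.93-fold and 1.65-fold. MKI67, a proliferation marker, fell 8.80-fold from 1031 ± 41.3 to 117 ± 20.1 (log2 -3.14, SE 0.16), RRM2, which makes deoxynucleotides, 13.7-fold (log2 -3.78, SE 0.22) and MYBL2, a cell cycle transcription factor, 12.2-fold (log2 -3.60, SE 0.18). FAM111B, a protease, and DTL, a gene of the S phase list, fell 12.9-fold and 12.8-fold.

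Glycolysis and hypoxia genes rose in 28 of 32 (30 adjusted over the list alone, camera adjusted p = 5.12e-23, 0.0421 with an estimated correlation) and ATF6 and XBP1 targets in 16 of 28, with 2 down (16 and 4, adjusted p = 0.000166, 0.0442 with an estimated correlation). NF-kB and inflammatory genes rose in 15 of 31 (15, adjusted p = 1.95e-05, 0.0421 with an estimated correlation) and fatty acid genes in 16 of 33, with FASN, the fatty acid synthase, up 2.11-fold (16, adjusted p = 8.82e-05, 0.0442 with an estimated correlation). Antigen presentation genes fell in 14 of 23 (14, adjusted p = 0.00013, 0.0442 with an estimated correlation). G2 and mitosis genes fell in 30 of 34 (30, adjusted p = 1.45e-15, adjusted p = 0.21 with an estimated correlation), and so did 30 of 34 S phase genes (30, adjusted p = 5.65e-15, adjusted p = 0.177 with an estimated correlation). The S100 and calcium-binding list rose in 13 of 33 (15, adjusted p = 0.00452, adjusted p = 0.0942 with an estimated correlation), with CALB1, a calcium buffer, at 51.8 ± 24.3 against 2.86 ± 2.54 and a change of 4.03 (3.24 without Resistant EV 3). PERK and ATF4 targets rose in 14 of 27 and fell in 7, with TRIB3, a stress-induced pseudokinase, up 2.06-fold (14 and 7, adjusted p = 0.0223, adjusted p = 0.428 with an estimated correlation). Cholesterol genes rose in 15 of 27 (16, adjusted p = 3.67e-06, adjusted p = 0.276 with an estimated correlation). YAP-TEAD targets fell in 10 of 23, with CTGF, a matricellular protein, down 2.85-fold (10, adjusted p = 0.0473, adjusted p = 0.127 with an estimated correlation), a call lost without Resistant EV 2 (0.06) or 3 (0.0807) and Resistant OC 1 (0.0815) or 3 (0.0561).

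EGFR fell 1.31-fold with OC in Resistant cells (log2 -0.39, SE 0.05) and AXL rose 2.38-fold (log2 1.25, SE 0.22). MET (log2 -0.08, SE 0.11, adjusted p = 0.593), DUSP6 (log2 -0.15, SE 0.22, adjusted p = 0.656) and ITPR1 (log2 -0.11, SE 0.18, adjusted p = 0.704) were not called, and the last pair changed sign without Resistant EV 1 (0.07 and 0.14). SERPINB4 stood at 59 ± 3.52 with no read in Resistant EV and SERPINB3 at 103 ± 23.2 with 2 reads there (log2 6.69 without Resistant EV 2, against 6.08), a pair of paralogs that share reads. AKAP2, a kinase anchoring protein, rose 32.8-fold (log2 5.04, SE 0.20), SPRR3, a squamous envelope protein, 17.1-fold (log2 4.09, SE 0.41), and SERPINA3, a protease inhibitor, 17.2-fold (log2 4.10, SE 0.68; 5.30 without Resistant EV 1 and 3.10 without Resistant EV 2). MATN3, a matrix protein, fell 13.7-fold and CKAP2L, a spindle protein, 16.7-fold (log2 -4.06; -2.66, -4.84 and -4.67 without Resistant OC 1, 2 and 3). The readthroughs C15orf38-AP3S2, MROH7-TTC4 and CHURC1-FNTB, whose reads overlap other genes, changed by 5.71, 5.27 and -4.85, calls that rested on single libraries and for the last pair on the processing. C15orf38-AP3S2 changed by 7.66 without Resistant EV 1 and 4.74 without Resistant EV 2 or 3. MROH7-TTC4 changed by 6.67 without Resistant EV 2 and 4.355 without Resistant OC 3, and CHURC1-FNTB by -6.545 without Resistant OC 2 and -3.997 without Resistant OC 3. C15orf38-AP3S2 lost its call without Resistant EV 2 (0.0767), Resistant EV 3 (0.0795) or Resistant OC 2 (0.0551), and MROH7-TTC4 without Resistant EV 1 (0.0651), Resistant EV 3 (0.0659) or Resistant OC 3 (0.0748) and under voom (0.0696). CHURC1-FNTB lost it without Resistant EV 1 (0.13) or 3 (0.0745) and Resistant OC 1 (0.134) or 3 (0.14), and under quantile normalization (0.0539), limma without trend (0.063), a pseudocount of 0.1 (0.061) and voom (0.0559). Limma called 5575 genes, 2472 higher and 3103 lower, 997 of them at least 2-fold; 5 of 15 lists called held with an estimated correlation and fry called 26.

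**Figure D3:**
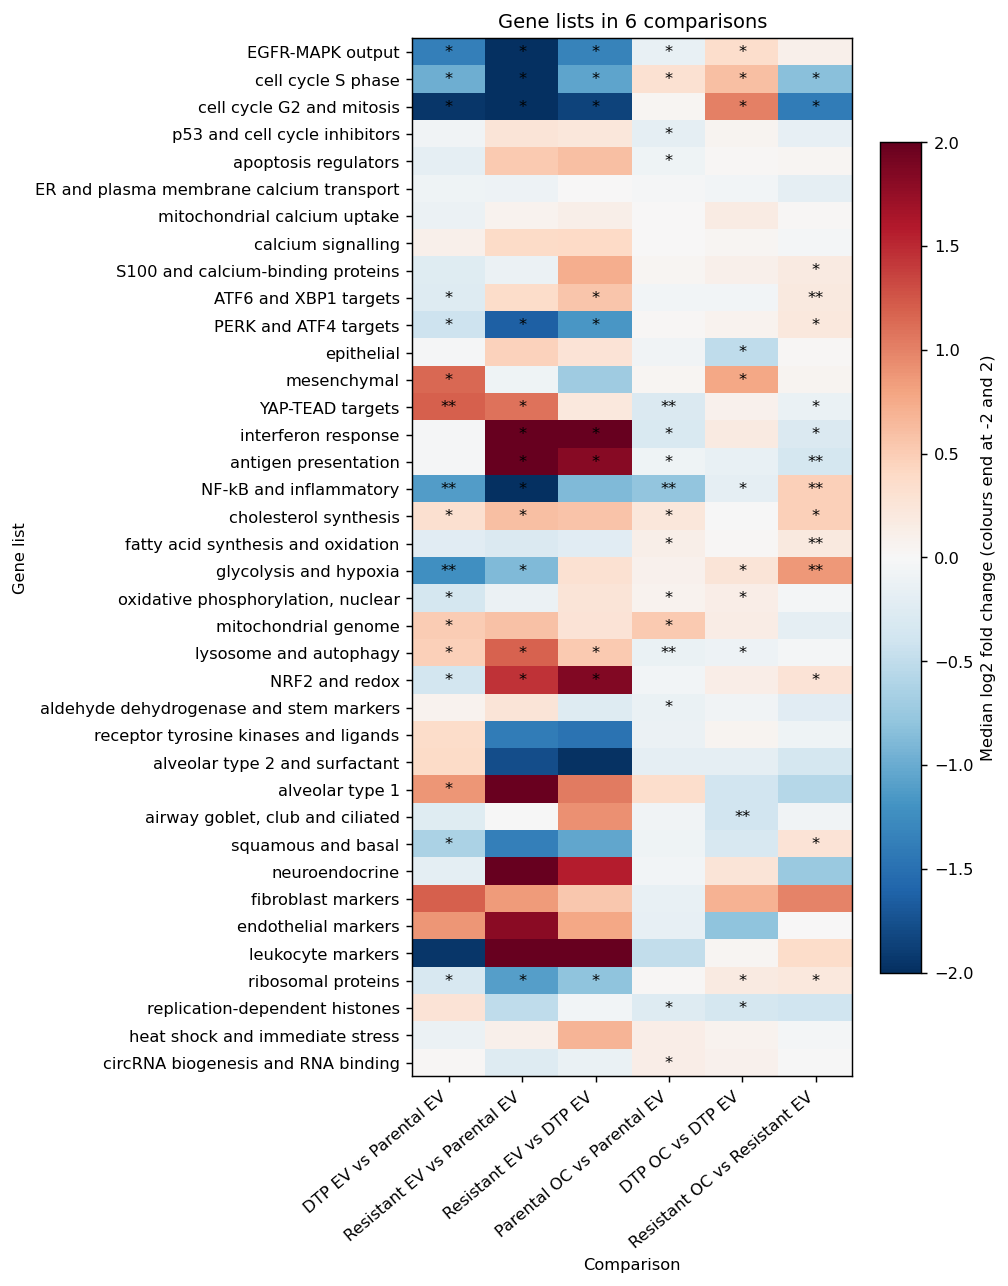
Median log2 fold change of 38 gene lists in 6 comparisons. An asterisk marks camera adjusted p below 0.05, and a pair of asterisks a call that also held with an estimated correlation.

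Whether the overexpression changed genes differently by state was tested as an interaction. By that test ATF6 counts themselves rose more with OC in Resistant than in Parental cells (by 1.32, adjusted p = 3.83e-08). For Resistant cells, a difference between states can therefore not be told apart from a stronger overexpression. Between DTP and Parental cells 1508 genes differed in their OC effect (830 higher and 678 lower in DTP; 238 at least 2-fold), and between Resistant and Parental cells 4603 (2157 and 2446; 1100 at least 2-fold). TNFAIP3, lower with OC in Parental cells, differed by 1.45 in DTP cells (adjusted p = 5.11e-09) and by 2.20 in Resistant cells (adjusted p = 7.58e-12). AXL differed by 1.88 in DTP cells (adjusted p = 0.00145) and 1.61 in Resistant cells (adjusted p = 0.000981), and HSPA5 by 0.96 in Resistant cells (adjusted p = 2.49e-09) and 0.07 in DTP cells (adjusted p = 0.393). The DTP count was 3142 without DTP EV 1, 962 without Parental EV 1, 987 without Parental EV 2 and 943 without DTP OC 3. NF-kB and inflammatory genes differed as a list in DTP (median 0.79, 0.00292 with an estimated correlation) and in Resistant cells (median 1.31, 0.000306 with an estimated correlation).

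Calcium genes, named in the series title, were looked at with the same lists. ATP2A2, the calcium pump of the ER, and ITPR1, its release channel, were lower in Resistant EV than in Parental EV by 2.26-fold and 2.12-fold, and with OC ATP2A2 changed past the threshold only in Resistant cells among the 3 states (1.29-fold up). Of 50 genes of ER and plasma membrane calcium transport, 13 rose and 16 fell in DTP EV against Parental EV (13 and 16 adjusted over the list alone), 20 and 21 in Resistant EV against Parental EV (20 and 21), 22 and 22 in Resistant EV against DTP EV (22 and 22), and with OC 0 and 3 in Parental (0 and 3), 4 and 8 in DTP (5 and 9) and 9 and 14 in Resistant cells (9 and 14). Of 18 genes of mitochondrial calcium uptake, 2 rose and 6 fell in DTP EV against Parental EV (2 and 5), 9 and 7 in Resistant EV against Parental EV (9 and 7), 7 and 5 in Resistant EV against DTP EV (7 and 5), and with OC 3 and 1 in Parental (4 and 1), 5 and 0 in DTP (5 and 0) and 4 and 2 in Resistant cells (4 and 2). Of 39 calcium signalling genes, 11 rose and 8 fell in DTP EV against Parental EV (11 and 8), 20 and 13 in Resistant EV against Parental EV (20 and 13), 19 and 12 in Resistant EV against DTP EV (18 and 12), and with OC 2 and 2 in Parental (2 and 2), 4 and 5 in DTP (4 and 5) and 10 and 12 in Resistant cells (10 and 13). Camera called none of these 3 lists in any of the 6 comparisons, with the smallest adjusted p, 0.0543, for mitochondrial uptake with OC in DTP cells. A further list, S100 and calcium-binding proteins, was called by camera with OC in Resistant cells (13 of 33 up and 3 down, 15 and 3 adjusted over the list alone, adjusted p = 0.00452, adjusted p = 0.0942 with an estimated correlation), and its OC effect was not called as different from that in Parental cells (interaction adjusted p = 0.103).

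Correlations across genes placed these changes side by side, with genes not being independent replicates. The OC effects correlated with r = 0.133 between Parental and DTP cells, -0.03 between Parental and Resistant, and -0.05 between DTP and Resistant, pairs that share no library. Higher with OC in both Parental and DTP cells were 234 genes and lower in both 283, against 87.2 and 108 expected with independent calls; 135 moved opposite ways against 197. For Parental and Resistant cells 635 genes moved opposite ways against 386 expected, with 165 higher and 284 lower in both against 149 and 250. For DTP and Resistant cells 843 moved opposite ways against 514, with 265 higher and 320 lower in both against 236 and 274. The DTP and Resistant changes from Parental EV correlated with r = 0.33, against 0.495 for unchanged groups that share 3 control libraries; their covariance was 0.931 against 0.0619 from sharing alone. Both changes were upward in 2507 genes and downward in 2666 (1682 and 1876 expected), figures that the shared controls raise.

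Circular RNAs were compared between 10 days of osimertinib and DMSO. A circRNA of ATF6 that joins exons 7 and 8 (circATF6_019, chromosome 1, 161771841 to 161789608 as the table gives it, 1 base beyond those exons) had 12, 15 and 6 back-splice reads in the DMSO libraries and 0 in each Osi library. The other circRNA of the ATF6 locus in the table, circATF6_024, spanning exons 2 to 7, had 0, 3 and 0 reads in Osi and none in DMSO, below the filter. circPION_012 had 87, 104 and 91 reads in DMSO and 9, 24 and 20 in Osi (log2 -2.64, SE 0.40). circTRAM1_023, from a gene of ER protein translocation, had 10, 16 and 17 reads in Osi, circPHLDB2_002, from a cortical adhesion gene, 14, 13 and 8, and circHIPK3_014, made of exon 2 of a kinase gene, 21, 7 and 11, each with none in DMSO. Total back-splice reads were 5603 ± 575 in DMSO and 7254 ± 109 in Osi (1.30-fold; exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give), and circRNAs with a read 1155 ± 85.9 and 1410 ± 68.9 (exact permutation p = 0.1). Neither measure is scaled, and the sequencing depth of these libraries was not known, so a difference in depth cannot be told apart from an effect of osimertinib.

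**Figure D4:**
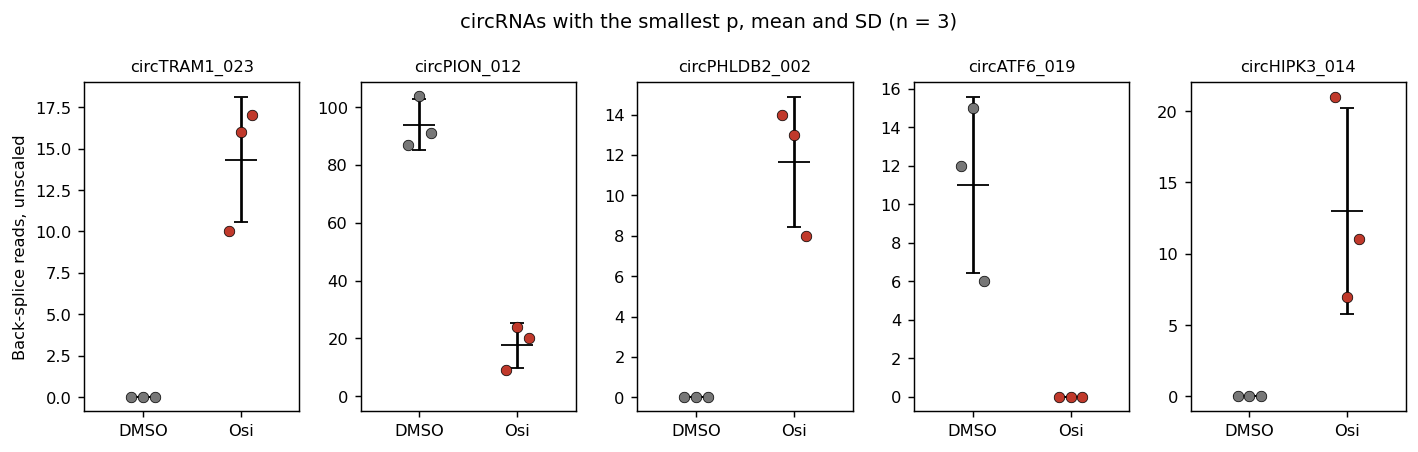
Back-splice reads of the 5 circRNAs with the smallest p between osimertinib and DMSO. Dots are single libraries, n = 3 per group; none passed adjusted p 0.05.

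No circRNA of 789 tested by limma passed adjusted p 0.05; the smallest adjusted p, 0.0594, was shared by 16 circRNAs, among them the 5 with the smallest p (TRAM1, PION, PHLDB2, ATF6_019 and HIPK3). At an unadjusted p under 0.05 were 111 circRNAs, 75 higher and 36 lower in Osi. The authors' own table gives adjusted p = 0.0351 for circTRAM1_023, circHIPK3_014 and circPHLDB2_002 and 0.047 for circATF6_019 (log10 fold change -1.05), 4 circRNAs below 0.05 from values not scaled for depth. It marks 146 circRNAs Up and 45 Down, 187 of them at adjusted p of 0.05 or more. Limma without trend called 36 circRNAs, no filter 19, no scaling 33 and a pseudocount of 0.1 44. The 5 circRNAs with the smallest p, circATF6_019 among them, passed adjusted p 0.05 in each of these settings. They did not pass under RLE size factors, quantile normalization, scaling by total circRNA reads or the replicate block, nor in the fits leaving out a library. Among all circRNAs listed, 8 had at least 2 reads in each DMSO library and 0 in every Osi library, and 29 were the reverse, in reads not scaled for depth. The labels do not say which circRNA was overexpressed as cATF6, so no value here is given for it.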

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

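Of the tests in this part, those of missing genes, library series, another cell population and an exchanged label, and the counts over other splits of the libraries, were chosen after the results were seen; the tests of admixed cells and of shared libraries were written before, except that Spearman's rho was added to the judgement of shared libraries after its values were seen.

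Genes named in the text for any OC comparison are listed here where the OC effect in DTP or Resistant cells differed from that in Parental cells by the interaction test (adjusted p below 0.05); values are log2 effects in DTP or Resistant cells minus that in Parental cells. Except for those always named, genes were picked by their OC change in Parental, DTP or Resistant cells, which can widen the difference. In DTP cells the effect was higher for AQP9 (4.30), CEACAM7 (2.47), IGFBP5 (2.38), GBP4 (2.13), AXL (1.88), DUSP1 (1.81), DUSP5 (1.78), CXCL8 (1.70), IL23A (1.59), CTGF (1.55), GDF15 (1.55), NUAK2 (1.53), TNF (1.47), TNFAIP3 (1.45), SERPINB4 (1.37), GADD45A (1.32), BBC3 (1.30), SQSTM1 (1.23), NDC80 (1.20), CYR61 (1.14), IFI6 (1.10), TTK (1.01), MKI67 (0.76), MET (0.57), CCND1 (0.56), NEU1 (0.47), ICAM1 (0.44), P4HA1 (0.43), FTH1 (0.38) and EGFR (0.24), and lower for KRT4 (-2.01), MINOS1-NBL1 (-1.93), TXNIP (-1.48), ARRDC4 (-1.42), LHX4 (-1.35), INSIG1 (-0.96), AGR2 (-0.79), SCD (-0.72), CCNE2 (-0.71), MUC1 (-0.71), MUC20 (-0.70), EGLN3 (-0.70), CDH3 (-0.56), MT-CO3 (-0.54), LCN2 (-0.41) and FASN (-0.26). In Resistant cells it was higher for SERPINB4 (6.55), SERPINB3 (6.31), AKAP2 (5.39), SERPINA3 (4.86), SPRR3 (4.73), CALB1 (3.97), DEFB4A (3.00), IL23A (2.75), CXCL8 (2.57), DUSP1 (2.41), TNF (2.40), CEACAM7 (2.27), TNFAIP3 (2.20), P4HA1 (2.08), ANGPTL4 (2.04), SQSTM1 (1.83), GDF15 (1.80), DDIT4 (1.76), AXL (1.61), NUAK2 (1.61), GADD45A (1.45), LCN2 (1.37), FTH1 (1.36), ATF6 (1.32), TNFAIP2 (1.31), TRIB3 (1.23), EGLN3 (1.20), BBC3 (1.18), NEU1 (1.16), ICAM1 (1.06), HSPA5 (0.96), TRIM22 (0.95), CYR61 (0.91), AGR2 (0.84), FASN (0.79), MUC20 (0.79), ELF3 (0.77), DUSP5 (0.76), LDHA (0.66), HYOU1 (0.61), CALR (0.55), SCD (0.52), ATP2A2 (0.40) and CDH3 (0.26). It was lower for FAM111B (-4.67), MATN3 (-4.17), RRM2 (-4.12), MYBL2 (-3.97), CKAP2L (-3.87), DTL (-3.74), IGFBP5 (-3.36), MKI67 (-3.33), TIMP3 (-2.60), TTK (-2.09), MINOS1-NBL1 (-1.97), CCNE2 (-1.93), PCNA (-1.47), BRCA1 (-1.44), TXNIP (-1.26), LHX4 (-1.22), COL5A1 (-1.19), ARRDC4 (-1.13), NDC80 (-1.08), MT-CO3 (-0.92), INSIG1 (-0.70) and EGFR (-0.22). SERPINB3, SERPINB4 and CALB1 rest on few reads in Resistant EV, and the OC change of CALB1 there was 4.03, or 3.24 without Resistant EV 3.

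Gene lists whose OC effect differed between states by camera are given by their median difference (log2). In DTP cells these were NF-kB (0.79) and YAP-TEAD (0.50), the only ones of 17 to hold with an estimated correlation, and G2 and mitosis (0.91), mesenchymal (0.67), EGFR-MAPK output (0.65), interferon (0.45), S phase (0.34), p53 (0.18), ribosomal proteins (0.15), apoptosis (0.10), PERK and ATF4 targets (0.10), circRNA biogenesis (-0.0298), fatty acid (-0.0314), cholesterol (-0.21), airway (-0.28), mitochondrial genome (-0.41) and epithelial (-0.42). In Resistant cells they were NF-kB (1.31) and ATF6 and XBP1 targets (0.24), which held with an estimated correlation, and glycolysis and hypoxia (0.75), EGFR-MAPK output (0.44), NRF2 and redox (0.31), squamous (0.31), PERK and ATF4 targets (0.26), ribosomal proteins (0.21), fatty acid (0.15), circRNA biogenesis (-0.19), mitochondrial genome (-0.74), S phase (-1.27) and G2 and mitosis (-1.54). Leaving out 1 library ended some of these calls. In DTP cells this held for S phase (0.0604 without DTP EV 2 and 0.0708 without DTP EV 3), p53 (0.0605 without DTP EV 1), ribosomal proteins (0.141 without DTP OC 1), circRNA biogenesis (0.0577 without DTP EV 1 and 0.0691 without DTP OC 1), apoptosis (7 libraries, 0.0516 to 0.0994) and fatty acid (6 libraries, 0.0537 to 0.0715), and in Resistant cells for squamous (0.0764 without Resistant OC 3).

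In entries left out of the comparisons, those named NewGene took 1.51% of all counts in the 6 Resistant libraries (1.49 to 1.54%) and 0.793% in the other 12 (0.734 to 0.846%). These are unnamed transcripts whose numbering does not match between the parts of the table, and whether the parts hold the same transcripts was not tested.

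The 6 Resistant libraries stand apart from the other 12. Of the genes called between Resistant EV and Parental EV, 3.71% are listed at 0 in every library of a series, so genes missing from 1 of the joined tables are not the whole cause. A shift between library series cannot be told apart from the state, since 0 states were prepared in both series. Another cell population under the Resistant label cannot be told apart from silencing, deletion or gaps in the table either: 50 genes with at least 300 counts in all 12 other libraries were listed at 0 in the 6 Resistant ones, 14 of them with zinc finger names (28% against 2.86% of 9299 such genes, Fisher exact two-sided p = 6.52e-11, chosen after the values were seen) and 14 on chromosome 19 (28% against 6.24%, p = 1.33e-06, likewise). Among these genes, all on chromosome 19 but UBE2M have zinc finger names, and all with such names but ZNF736 lie on chromosome 19. The zinc finger and chromosome 19 tests are therefore not separate evidence. Both also count genes as independent, which genes of 1 chromosome need not be. CT83, DYNLT3, FGF13, GPRASP2, MAGED4B, MID1IP1, XAGE1A and XAGE1B, also listed at 0, lie on chromosome X, whose share was not tested. A change of state under osimertinib, the biological explanation the design gives, stays open and untested.

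Library DTP EV 1 lies apart from DTP EV 2 and 3, toward DTP OC. Its scaled ATF6 count of 3272 matches the EV libraries, against 20860 ± 1920 in DTP OC, so an exchanged label with an overexpressing library is excluded. Admixed cells in the Parental state, as the only difference, would need 1 share of Parental RNA for all genes. The 226 genes lower in DTP EV 2 and 3 needed a median of 13.2% (bootstrap interval 11.3 to 14.5%, quartiles 4.29 and 20.2%). The 188 higher genes needed 39.1% (35.6 to 45.4%, quartiles 14.4 and 58%). The medians differed by 25.9 points (26.8 with RLE size factors and 24.3 with no scaling), so 1 share did not serve both sets. The bootstrap drew genes as independent, and admixture beside another difference was not tested. No biological explanation was tested for this library, and a less advanced drug-tolerant state may be one.

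The OC effect in DTP cells ran against the DTP change (r = -0.20 over 15155 genes), but both use the DTP EV libraries, and unchanged groups sharing them would give -0.50. Against the mean DTP change of EV and OC, r was 2.89e-05. Shared noise cancels there only if EV and OC spread alike, but chi-square per degree of freedom between replicates was 54.3, 53.7 and 16.6 in DTP EV and 16.5, 10.1 and 10.1 in DTP OC, so it need not cancel. The value ranged from -0.13 to 0.04 leaving out 1 library (-0.13 without DTP EV 1). Spearman's rho was -0.12 and genes above the median level gave -0.21, and without DTP EV 1 these were -0.22 and -0.33. All 3 measures are negative there, but 2 EV libraries then stand against 3 OC libraries, so noise need not cancel either, and shared DTP EV libraries may or may not be the whole cause. For Resistant cells, which share no library with that change, r was -0.11, and for Parental cells 0.09.

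Other splits of the same libraries were counted for each comparison. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split gave 8647 genes for DTP EV against Parental EV (highest other 1), 12479 for Resistant EV against Parental EV (0), 12239 for Resistant EV against DTP EV (1), 2135 for Parental OC (2), 2785 for DTP OC (1031) and 5575 for Resistant OC (32), in each case 1 of 10 splits as large. The split with 1031 genes put DTP EV 1 with DTP OC 1 and 3, which points to a structure of the samples. For circRNAs, with 0 calls, 10 of 10 splits gave as many (highest other 1), which a count of 0 fixes in advance. At unadjusted p below 0.05 the real split had 111 circRNAs and the 9 others 24 to 45. For the interaction of OC with Resistant, 1 of 100 drawn splits reached 4603, the real one (highest other 2658). The next highest splits, with 2658, 2550, 2547 and 2451 genes, all kept the real Resistant grouping. Splits for either interaction also break up the OC effect within a state. They therefore cannot separate a difference between states from an OC effect in 1 state, and no conclusion on chance is drawn. For the interaction with DTP, 4 of 100 reached 1508: the highest, 3582, exchanged EV and OC in Parental cells and so tests the sum of the effects. Those with 2432 and 1554 put DTP EV 1 with a pair of DTP OC libraries. The share is under 0.05, but these splits follow the samples' own structure.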

How the results depend on the processing

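Tests added after the data were seen were voom, leaving out genes listed at 0 in a whole series, leaving out the 6 Resistant libraries, no scaling and scaling by total reads for circRNAs, and leaving out each library for the lists. The others were chosen before.

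Over RLE size factors, quantile normalization, no filter, limma without trend, a pseudocount of 0.1, the replicate block and voom, the counts of called genes in the 6 comparisons and 2 interactions stayed within 1.5 times the reported ones. So did those of the 3 comparisons and 1 interaction that a fit without the 6 Resistant libraries allows. Replicate numbers do not pair the libraries. With the replicate number as a block, 8549, 12459, 12200, 1961, 2625 and 5466 genes were called in the order of the text, and 1362 and 4444 in the interactions; the block ended 1 named call, ATF6 between DTP EV and Parental EV (log2 0.16, adjusted p = 0.0563; 0.00459 to 0.112 over its alternatives). Without genes at 0 in a whole series, Resistant EV differed from Parental EV in 11986 genes and from DTP EV in 11721.

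With only the groups compared in the fit, Parental OC gave 5698 genes and DTP OC 65. Spreads then come from 6 libraries, and those of DTP EV differ most; the cause was not tested. A 2-fold minimum left 2699, 7393, 6917, 168, 266 and 997 genes and 238 and 1100 in the interactions, by construction. Leaving out 1 library gave 1389 to 1569 genes for Parental OC, 1485 to 4654 for DTP OC and 943 to 3142 for the interaction with DTP, with the highest values of the latter pair without DTP EV 1.

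Of 202 named gene results, 2888 alternative values kept direction and side of the threshold, 90 lost their call (54 of them leaving out a library, 20 with only the groups compared), 2 gained one and 5 changed sign. Under quantile normalization EGFR in DTP EV against Parental EV was 0.0536, HSPA5 in Resistant EV against DTP EV -0.237 and ATP2A2 with OC in Parental cells 0.0185. Without Resistant EV 1, DUSP6 and ITPR1 with OC in Resistant cells were 0.0660 and 0.139 (from -0.244 and -0.263 without Resistant EV 3). The cause was not tested.

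With an estimated correlation 3, 0, 0, 3, 1 and 5 lists were called in the 6 comparisons and 2 and 2 in the interactions, by construction, since correlated members widen the null. Fry, which does not compare a list with other genes, called 31, 35 and 35 lists between states, 26 with OC in Resistant cells and 22 in the interaction with Resistant. Of 113 list calls, 97 were lost with an estimated correlation, 41 values leaving out a library and 10 with fry.

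Spearman's rho in place of r gave 0.181 for OC effects in Parental and DTP, -0.0703 in Parental and Resistant, and 0.317 for the DTP and Resistant changes. Genes above the median level gave 0.283, -0.0848, 0.403 and, for OC in DTP and Resistant, -0.0889. For circRNAs, no filter called 19, limma without trend 36, a pseudocount of 0.1 44 and no scaling 33, against 0 reported; the cause was not tested. RLE, quantile normalization, total reads, the block and leaving out a library also called 0. In simulated data 2.99% of 2-fold and 46.3% of 4-fold changes were recovered. Settings of DESeq2 and edgeR were not run, nor the comparisons of Osi with DMSO by gene and with the DTP change, whose columns could not be tied to samples.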

Other observations

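No test in this part was chosen after the result was seen. Camera called no marker list of the following cell types between Resistant EV and Parental EV: leukocyte markers rose in 4 of 7 with 1 lower (median 2.93, adjusted p = 0.22), fibroblast markers in 4 of 11 with 1 lower (0.86, adjusted p = 0.187), endothelial markers in 4 of 7 with 1 lower (1.81, adjusted p = 0.319) and neuroendocrine markers in 4 of 7 with 3 lower (2.98, adjusted p = 0.668). Fry, which does not compare a list with other genes, called these 4 (adjusted p = 1.42e-10, 8.39e-09, 1.77e-08 and 0.0226, the last as lower). In DTP EV against Parental EV alveolar type 1 markers rose in 8 of 13 (0.88, adjusted p = 0.019, lost with an estimated correlation at 0.304).

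In the circRNA table the spliced length exceeds the genomic span for 1062 of 2997 circRNAs. circATF6_019 extends 1 base beyond exons 7 and 8 of the principal ATF6 transcript at its listed start, and its spliced length of 407 equals those exons. circATF6_024 spans exons 2 to 7, which hold 827 bases against a listed 3674, and circPION_012 has a listed spliced length of 1513 against a span of 1083.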
